A study of Mus musculus with 2 samples.

How the data were processed

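Chromatin accessibility was profiled in liver of mouse embryos at embryonic day 14.5 by ATAC-seq, in which a transposase loaded with sequencing adapters cuts and tags open chromatin. Per the labels, 2 biological replicates were made, 1 from the pooled livers of 24 embryos and 1 from those of 34 embryos, of mixed sex, with Nextera tagmentation and a size range of 200 to 750 bp. The labels describe both as the same tissue and age, so there was 1 group and no contrast between groups. The samples were taken as separate pools because the labels give different embryo numbers and biological replicate numbers.

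The 12 deposited peak lists were used, 3 per replicate and 6 for the whole series. The whole-series lists were made from alignments of both replicates, per the file headers of the accompanying text descriptions. The lists differed in stringency: ranked by the irreproducible discovery rate (IDR), thresholded on it, conservatively thresholded on it, replicated, and pseudoreplicated. The coordinates are on mm10, per the labels. The aligner, the peak caller, their versions, the handling of the transposase offset and the IDR threshold were not given in the sources used here. The signal value of each summit was the authors' own, and the deposited descriptions did not say what it was relative to. The −log10 p of each summit was also the authors' value as deposited. The display score deposited with each summit was not tested, and its lowest value was 540 in every IDR-thresholded list. A further deposited column of the ranked lists, with no description, was not used in any comparison.

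A deposited interval could carry several summits. Intervals with the same start and end were therefore merged into 1 region represented by its summit with the highest signal, a choice made after the files were seen; results with every summit were computed as an added alternative. Only regions on the 19 autosomes, X and Y entered the comparisons. The lists held no read counts, so the sequencing depth of each library was unknown, and signal values were used only to rank or describe regions within a list. Percentages of regions or genes carry 95% Wilson intervals, which cover counting error only.

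The annotation was GENCODE vM21 on GRCm38.p6, the assembly that mm10 names, with 21911 protein-coding genes of unique symbol. A promoter was the transcription start site (TSS) of any annotated transcript of a gene ± 1 kb. A gene was called open when an IDR-thresholded region of each replicate overlapped its promoter by at least 1 bp. A distal region was a region of the pooled IDR-thresholded list whose summit lay over 1 kb from every TSS. Promoter calls used the whole region and distal calls its summit, so 1 region could count as both, as beside Hbb-bs. Overlaps were computed with bedtools 2.31.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Sequence was read with pysam 0.24.0 after indexing with samtools 1.23.1, and figures were drawn with matplotlib 3.10.9.

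Reproducibility was the percent of regions of a replicate overlapping a region of the other by 1 bp, with a chance level from 100 circular shifts within each chromosome. Promoter accessibility of 23 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Distal regions within 50 kb of the gene start were averaged per list and set against 10000 random lists matched on decile of gene density, with a two-sided permutation p adjusted in the same way. The smallest p that these permutations can give is 0.0002, and its adjusted value here was 0.00092. The 22 motifs were searched on both strands within 100 bp of distal summits and in windows of the same width centred 1000 bp to each side that overlapped no region, and were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05 throughout. Genes and regions are not replicates, so these p-values describe the 2 libraries.

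The gene lists covered erythroid regulators and red cell membrane proteins, globins, haem synthesis and iron import, secreted proteins of hepatoblasts (the embryonic precursors of hepatocytes and bile duct cells), hepatoblast transcription factors, postnatal hepatocyte metabolism, oncofetal growth genes, haematopoietic progenitors, megakaryocytes, macrophages, granulocytes, lymphoid cells, endothelium, stellate and mesenchymal cells, cholangiocytes, neurons, muscle, other epithelia, germline, cell cycle, housekeeping, olfactory receptors and Hox clusters. Hoxa9 and Hoxa10 stood in both the progenitor and the Hox lists, and no other gene stood in 2 lists. Members without a protein-coding match in the annotation were left out, which gives the list sizes stated with each result.

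The text names, for each list except the olfactory receptors, which are given as counts, the 3 open members with the highest mean promoter signal and up to 2 members, in alphabetical order, with no promoter region in either replicate. It also names the 10 genes with the highest promoter signal, the 10 with the most distal regions within 50 kb, and the nearest protein-coding gene of each of the 10 strongest distal regions. Other genes named were chosen after their values were seen and are marked as such. The lists, motifs, tests, naming rule and most alternatives were fixed before the data were examined. Alternatives covered the overlap rule, the list, the promoter width, the distance, the motif window, GC-matched and CpG-matched backgrounds, and each replicate left out.

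The tests were checked on simulated data. For promoter lists over 21911 genes, all 20 lists simulated as 95% open and all 20 simulated as 5% open were recovered, and 0 of 60 unchanged lists were called. For distal regions near lists over 21911 genes, 10 of 10 lists with added regions were recovered and 1 of 20 unchanged lists was called. For motifs over 4000 windows, 6 of 6 planted motifs were recovered and 1 of 16 others was called.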

Results

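Open chromatin was mapped by ATAC-seq in the liver of mouse embryos at embryonic day 14.5, when the organ is a site of blood formation as well as of hepatoblast growth. The series held 1 group of 2 replicates, replicate 1 from 24 pooled embryos and replicate 2 from 34, and no other tissue or age for contrast. The IDR-thresholded lists held 16207 accessible regions covering 11.9 Mb in replicate 1, 24189 regions covering 18.5 Mb in replicate 2, and 25955 regions covering 19.9 Mb in the pooled data. The depth of the libraries is unknown because the lists carry no read counts. All coordinates are on mm10. The design allows the replicates, the lists and fixed groups of genes and motifs to be compared within this tissue.

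The first comparison asked how far the replicates gave the same regions. Of the replicate 1 regions, 98.5% (95% Wilson interval 98.3 to 98.7%, 15964 of 16207) overlapped a replicate 2 region, while 64.8% (64.2 to 65.4%, 15666 of 24189) of the replicate 2 regions overlapped a replicate 1 region. Circularly shifted regions overlapped in 1.41% and 0.958% of cases on average over 100 shifts. The replicates shared 61.5% of the bases that either list covered. At open promoters, the same asymmetry appeared: 9661 of 21911 protein-coding genes (44.1%) were open in both replicates, 1359 in replicate 2 alone and 35 in replicate 1 alone. With both lists limited to the same number of strongest regions, the shares were 85.8% for replicate 1 and 83.8% for replicate 2.

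Regions found in both replicates kept their order of strength. Over 15572 matched pairs of regions, Spearman's rho of the authors' signal value was 0.912. This is a correlation across regions, which are not independent replicates, so no p is given. The most accessible promoters were named by their mean signal over both replicates, so their strength in both lists is largely set by that choice. The gene 6720489N17Rik, on chromosome 13, had a signal of 26.7 in replicate 1 and 29.3 in replicate 2. Golga7 had 27.8 and 25.4 at an alternative start 10.8 kb inside the gene, against 12.5 and 15.5 at its gene start. A promoter signal is the highest over all annotated starts of a gene, and it also lay over 2 kb from the gene start for Arhgap29, Hint3, Steap3, Rxra, Hpd, Runx1, Vwf, Itga2b, Lck and Gata3. Of these, Hint3, Hpd, Vwf, Lck and Gata3 had no thresholded promoter region at the gene start in either replicate. Runx1 and Itga2b had none there in replicate 1. The other genes among the 10 highest were Kifap3, Arhgap29, Dlg2, Tmem126b, Rbm25, Scfd1, Zfp54 and Hint3. Dlg2 and Tmem126b are neighbours on chromosome 7 that share 1 region at their adjoining starts, so their values are the same measurement.

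Regions found in a single replicate were weak, narrow and mostly away from promoters. The 8523 regions of replicate 2 with no counterpart in replicate 1 had a median signal of 6.64, against 14.1 for the shared regions of the same list, and a median width of 463 bp against 901 bp. Promoters held 30.3% of them and 62.6% of the shared regions. The 243 regions of replicate 1 alone had a median signal of 7.29 against 11.8, and 29.6% lay at promoters against 62.7%. In the looser IDR-ranked lists of the other replicate, 74.7% of the replicate 2 regions and 95.9% of the replicate 1 regions had a counterpart, leaving 2158 and 10 with none.

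The deposited lists overlapped widely without nesting fully. The conservative pooled list held 22913 regions, the replicated list 44947 and the pooled pseudoreplicated list 51305. The pooled IDR-thresholded regions lay almost entirely in the pseudoreplicated list (99.9%, 25917 of 25955), and 82.8% of them (21490) overlapped a conservative region. Of the conservative regions, 93.8% (21490 of 22913) overlapped the pooled IDR-thresholded list, and 93.2% of the replicated regions overlapped the pseudoreplicated list. Replicate 1 regions made up less of the pooled list than those of replicate 2, with 60.7% of pooled regions overlapping a replicate 1 region and 88.7% a replicate 2 region. The pseudoreplicated lists of replicate 1 and replicate 2 held 30910 and 47124 regions.

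Accessible regions concentrated at gene starts. Of the 25955 pooled regions, 49.3% (95% Wilson interval 48.7 to 49.9%) had their summit within 1 kb of a TSS, against 6.19% ± 0.251 (SD over 100 circular shifts), which is 7.96 times the shifted share. Introns held 28.9% of summits and exons 3.02%, against 39.2% and 3.32% after shifting, and intergenic sequence held 18.8% against 51.3%. Promoter regions were also stronger, with a median signal of 12.9 against 8.28 in intergenic sequence. The promoter share was 35.1% in the looser pooled pseudoreplicated list and 62.2% in the replicate 1 list alone.

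Promoter accessibility was then compared between gene lists fixed for the cell types that an embryonic liver could hold. A member said to have no region, or none, had no thresholded promoter region in either replicate and could still have a weaker region in the looser lists. A region counted for every gene whose promoter it overlapped, so an open call, or its signal, can come from the start of a neighbouring gene. Erythroid genes were open almost without exception. Regulators and membrane proteins of red cells were open at 28 of 29 genes (96.6%, 95% Wilson interval 82.8 to 99.4%; odds ratio 35.6; adjusted p = 1.38e-08, Fisher's exact test). The highest values were at Trim10 (chromosome 17, 36869574 to 36877833; signal 22.6 in replicate 1 and 19.9 in replicate 2), at Epb42, which encodes a red cell membrane protein (chromosome 2, 121017891 to 121037072; 20.9 and 21.3), and at Spta1, which encodes erythroid spectrin (chromosome 1, 174172776 to 174248450; 22.2 and 19.3). The Spta1 values came from a region before its gene start (174171573 to 174171955), and a weaker region at the start itself had 6.51 and 8.30. The list member that was not open was Gfi1b, which encodes a transcriptional repressor that acts in the erythroid and megakaryocytic lineages. Gfi1b had no thresholded promoter region in either replicate but 6 distal regions within 50 kb. Its promoter was in both pseudoreplicated lists at signals of 3.02 and 2.81.

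Genes of haem synthesis and iron import were open at 17 of 17 (adjusted p = 3.42e-06, Fisher's exact test), led by Cpox, an enzyme of the haem pathway (19.2 and 16.6), Slc25a37, the mitochondrial iron carrier (16.7 and 17), and Steap3, a ferrireductase of iron uptake (16.1 and 14.5). Random genes of the same promoter CpG content would be open at 36.2% for the erythroid list and 48.9% for the haem list, and both lists stayed higher against them (adjusted p = 0.000575 each, the smallest these permutations allow). Among regions above the median signal the haem call was lost (odds ratio 1.74, adjusted p = 0.285, Fisher's exact test). The median promoter signal was 12.6 for open erythroid genes and 14.6 for all open genes. In the pooled pseudoreplicated list the erythroid median, 12.7, was above 86.1% of random lists of open genes of the same CpG content (mean 10.7).

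Among the globins, adult genes had promoter regions in the thresholded lists of both replicates and embryonic ones had none there. Of 10 globin genes 4 were open, all adult-type: Hbb-bs (10.3 and 8.97), Hbb-bt (10.2 and 8.24), Hba-a2 (7.31 and 8.95) and Hba-a1 (5.26 and 6.36). Hba-x and Hbb-bh1, which are expressed in primitive red cells of the earlier embryo, had no thresholded promoter region in either replicate. The same held for Hbb-y, Hbb-bh2, Hbq1a and Hbq1b, and together with Hba-a1 these were named after their values were seen. In the pooled IDR-thresholded list 5 of the 10 had a promoter region, Hbq1b being the addition, and in the looser pooled pseudoreplicated list 7 of the 10 had a promoter region, Hbb-bh1 among them. The list as a whole passed no test against other genes (adjusted p = 1, Fisher's exact test) or against genes of the same CpG content (11.9% open on average, adjusted p = 0.0509, permutation), and its odds ratio of 0.845 turned to 1.84 with promoters of ± 2 kb and to 3.81 against the same CpG deciles. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so their separate values are uncertain.

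**Figure D1:**
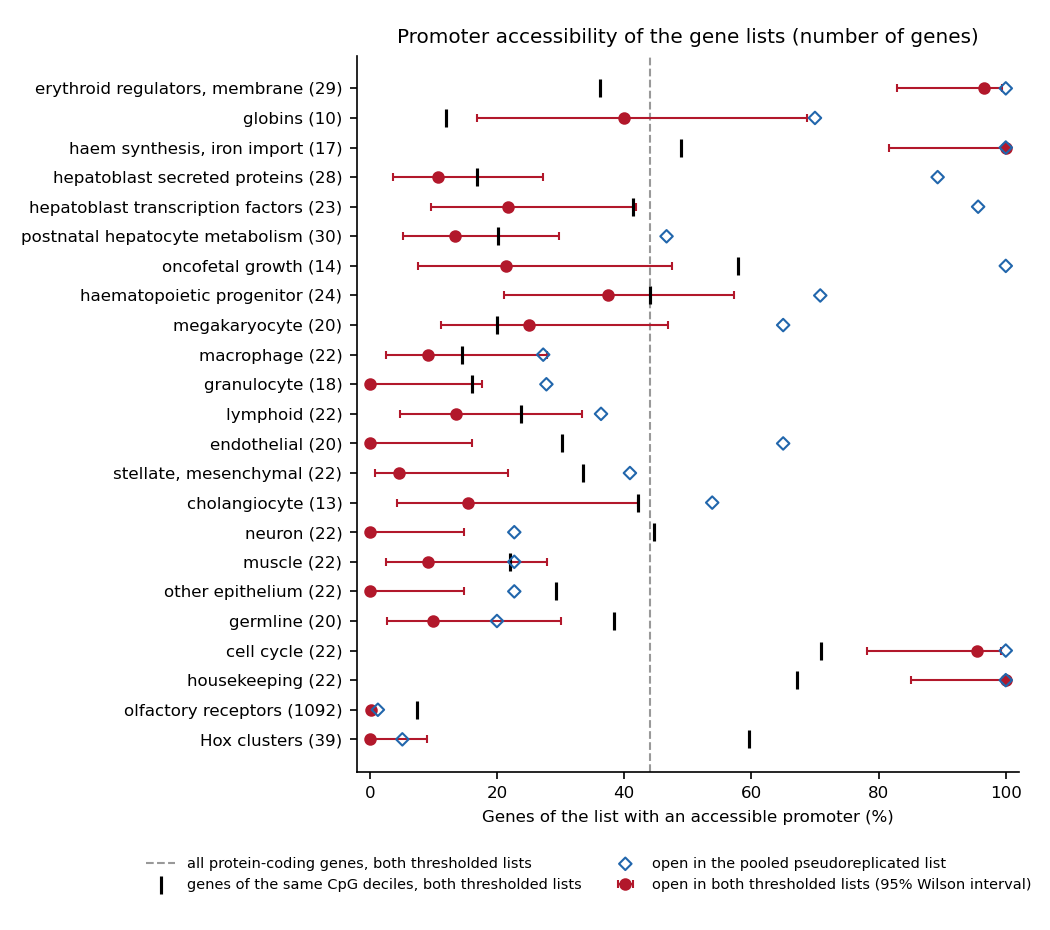
Percent of the genes of each list (list size in parentheses) with an accessible promoter in both IDR-thresholded lists (red circles, 95% Wilson intervals), in genes of the same CpG deciles (black ticks) and in the pooled pseudoreplicated list (blue diamonds). The dashed line marks the 44.1% of all protein-coding genes; erythroid and haem genes reach 96.6% and 100% in the thresholded lists, and hepatoblast secreted proteins are at 10.7% in the thresholded lists of both replicates and at 89.3% in the pooled pseudoreplicated list.

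Few hepatoblast genes were open in the thresholded lists of both replicates, and more were open in the pooled lists. Promoters of secreted hepatoblast proteins were open at 3 of 28 genes (10.7%, 95% Wilson interval 3.71 to 27.2%; odds ratio 0.152; adjusted p = 0.000381, Fisher's exact test): Apoh (14.2 and 15.8), Plg, which encodes plasminogen (5.68 and 9.16), and Apoa1 (5.33 and 5.04). The Apoh gene start had a CpG observed-to-expected ratio of 0.745, against a list median of 0.240. Whether its region belongs to a neighbouring gene was not checked. Afp and Alb, the genes of alpha-fetoprotein and albumin, had no thresholded promoter region in either replicate, although 3 and 4 distal regions lay within 50 kb of them. Both lie on chromosome 5, with starts at 90490737 and 90460897, so their windows overlap and the same regions can count for both. Hepatoblast transcription factors were open at 5 of 23 (adjusted p = 0.0448, Fisher's exact test), led by Foxa3 (14.4 and 15.0), Rxra (11.2 and 13.3) and Tbx3 (9.16 and 9.10), while Creb3l3 and Foxa2 had no thresholded promoter region.

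In the pooled IDR-thresholded list, 13 of 28 secreted-protein genes and 14 of 23 transcription factor genes had a promoter region, against 11250 of all 21911 genes. In the pooled pseudoreplicated list, 25 of 28 secreted-protein genes (89.3%) and 22 of 23 transcription factor genes (95.7%) had a promoter region, against 59.9% of all genes. In that list Alb reached a signal of 3.0 and Afp still had no promoter region. The lower share of the secreted-protein list was lost against genes of the same CpG content (16.8% open; adjusted p = 0.589, permutation) and turned to an odds ratio of 2.18 in the pseudoreplicated lists of both replicates (adjusted p = 0.0811, Fisher's exact test) and to 1.14 in the conservative list (adjusted p = 0.889). It rested on replicate 1, where 4 of the 28 genes were open against 14 in replicate 2, and with replicate 2 alone the adjusted p was 1. By the same exact test, the call on transcription factors was lost when either replicate was left out (adjusted p = 0.918 without replicate 1 and 0.232 without replicate 2) or gene starts alone were used (0.101), and the odds ratio was 1.36 in the pseudoreplicated lists and 1.08 in the conservative list. Against genes of the same CpG content the transcription factor list stayed lower (41.4% open on average, adjusted p = 0.0463, permutation).

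Genes of postnatal hepatocyte metabolism were open at 4 of 30 (adjusted p = 0.00112, Fisher's exact test; adjusted p = 0.489 against genes of the same CpG content). Gls2 (14.7 and 16.7), Glul, which encodes glutamine synthetase (15.6 and 15.0), and Hpd (12 and 14.3) were open, and Abcb11, the bile salt export pump, and Aldob were not. The Hpd values came from a region 10.9 kb from its gene start, and the gene start itself had no thresholded region in either replicate. Oncofetal growth genes were open at 3 of 14, namely Cdkn1c (8.86 and 14.1), Lin28b (8.30 and 13.2) and Igf2bp3 (5.77 and 6.33), with no thresholded promoter region at Dlk1 or Gpc3, which had promoter signals of 4.79 and 5.27 and of 5.05 and 9.81 in the pseudoreplicated lists. This share did not pass the test against other genes (adjusted p = 0.125, Fisher's exact test) but lay under the 57.9% of genes of the same CpG content (adjusted p = 0.00836, permutation). In the pooled pseudoreplicated list 14 of 14 had a promoter region, and in the pseudoreplicated lists of both replicates the odds ratio turned from 0.346 to 3.2 (adjusted p = 0.0837, Fisher's exact test).

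Fewer members of the other blood lineage lists were open, a contrast with the erythroid list that was not itself tested. Haematopoietic progenitor genes were open at 9 of 24 (adjusted p = 0.570) and megakaryocyte genes at 5 of 20 (adjusted p = 0.125), both by Fisher's exact test. Runx1 (14.3 and 13.1), Lyl1 (10.7 and 11.2) and Hlf (8.08 and 12.9) led the progenitors, where Angpt1 and Cd34 had no region. Vwf (14.5 and 15.5), Gp1ba (10.6 and 12.1) and Itga2b (8.56 and 9.87) led the megakaryocyte genes, where Clec1b and F2rl2 had none. At the gene start itself, Vwf had no thresholded region in either replicate, and Runx1 and Itga2b had none in replicate 1. Among regions above the median signal both lists were lower than other genes (odds ratio 0.108, adjusted p = 0.0104, and 0.130, adjusted p = 0.0273, Fisher's exact test), and the megakaryocyte list was also lower under 4 other settings. The progenitor odds ratio of 0.761 turned to 1.03 in the pseudoreplicated and 1.17 in the conservative lists, and the megakaryocyte odds ratio of 0.422 to 1.3 against the same CpG deciles.

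Macrophage genes were open at 2 of 22 (adjusted p = 0.0012, exact test), namely Slc40a1, the iron exporter (12.3 and 13.4), and Mertk (7.91 and 10.2), with none at Adgre1 or Aif1. Lymphoid genes were open at 3 of 22 (adjusted p = 0.00564, exact test), namely Vpreb1 (16.9 and 16.3), Lck (11.9 and 10.1) and Gata3 (9.44 and 12.5), with none at Blk or Cd19. Lck and Gata3 had no thresholded region at the gene start itself in either replicate. Granulocyte genes, such as Camp and Cebpe, were open at 0 of 18 (adjusted p = 8.67e-05, exact test). These were Fisher's exact tests, and all 3 calls were lost against genes of the same CpG content (adjusted p = 0.695, 0.385 and 0.0681, permutation).

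Genes of the supporting cells were rarely open at the same threshold. No endothelial gene was open in both replicates (0 of 20, adjusted p = 2.77e-05, exact test), Cdh5 and Clec4g among them, although 4 were open in replicate 2 alone and 13 had a region in the pooled pseudoreplicated list. With the pseudoreplicated lists of both replicates the endothelial call was lost (adjusted p = 0.306, exact test). Stellate and mesenchymal genes were open at 1 of 22 (adjusted p = 0.000216, exact test), Reln (4.92 and 4.57), with none at Acta2 or Col1a1. Cholangiocyte genes were open at 2 of 13 (adjusted p = 0.0586, exact test), of which Tspan8 lay at the 99.6th percentile of open promoters (23.7 and 24.7) and Jag1 a weaker one (6.53 and 10.1), and Bicc1 and Cftr had none. These tests were Fisher's exact tests; against genes of the same CpG content the cholangiocyte list was lower (adjusted p = 0.0463, permutation).

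Genes of tissues outside the liver were rarely open, and genes used by all cells nearly always were. Neuronal genes (0 of 22, adjusted p = 9.16e-06; Dcx and Elavl3 are examples), other epithelial genes (0 of 22, adjusted p = 9.16e-06; Cdx2, Cpa1), Hox genes (0 of 39, adjusted p = 1.77e-09; Hoxa1, Hoxa10) and olfactory receptor genes (3 of 1092, adjusted p = 1.19e-276) were lower by Fisher's exact test. Muscle genes were open at 2 of 22 (adjusted p = 0.0012), Mylpf (11 and 11.1) and Tnnc1 (6.32 and 8.55), with none at Acta1 or Actc1, and this call was lost against genes of the same CpG content (adjusted p = 0.205, permutation). Germline genes were open at 2 of 20 (adjusted p = 0.0034, exact test), Gdf9 (15.9 and 13.6) and Dazl (11.6 and 16.9), with none at Bmp15 or Ddx4.

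Cell cycle genes were open at 21 of 22 (adjusted p = 1.97e-06, exact test), led by the mitotic cyclin genes Ccnb2 (20.8 and 22.7) and Ccnb1 (17.7 and 21.0) and by the replication factor gene Mcm3 (20.2 and 19.8). Housekeeping genes were open at 22 of 22 (adjusted p = 8.51e-08, exact test), led by Pgk1 (19.2 and 19.4), Atp5b (16.3 and 18.7) and Psmb2 (17.4 and 16). In all, 4 of the 23 lists were higher than other genes and 14 were lower. Promoter CpG content separated open from closed genes strongly, from 3.6% open in its lowest decile to 84.5% in its highest.

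Distal accessible regions were more numerous near globin, erythroid, haem and progenitor genes, and also near cell cycle and housekeeping genes. The pooled list held 13152 distal regions (50.7%), and a protein-coding gene had 0.982 of them within 50 kb on average. Globin genes had 8.30 ± 2.41 (SD over 10 genes) against 1.28 in random lists of the same gene density (95% range 0.40 to 2.5), erythroid genes 3.41 ± 2.61 (29 genes) against 0.985 (0.483 to 1.62), and haem and iron genes 3.24 ± 2.93 (17 genes) against 1.08 (0.412 to 1.94). Each had an adjusted p of 0.00092 by permutation, the smallest these permutations allow. Haematopoietic progenitor genes had 1.958 against 0.843 (adjusted p = 0.0092, permutation).

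Globin genes lie in clusters and share their distal regions, so their list holds 2 separate neighbourhoods. Round the beta-globin cluster (chromosome 7, 103812524 to 103853216), 12 distal regions lay within 50 kb, 9 of them with a GATA motif, 4 with a GATA motif paired with an E-box and 2 with an NFE2 motif. Round the alpha-globin cluster (chromosome 11, 32276400 to 32300873), there were 7, of which 4 had a GATA motif. The strongest distal signals were 15.1 at the beta and 17.2 at the alpha cluster, and the regions of the beta cluster lay on the far side of the embryonic genes as well as beside Hbb-bs and Hbb-bt.

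**Figure D2:**
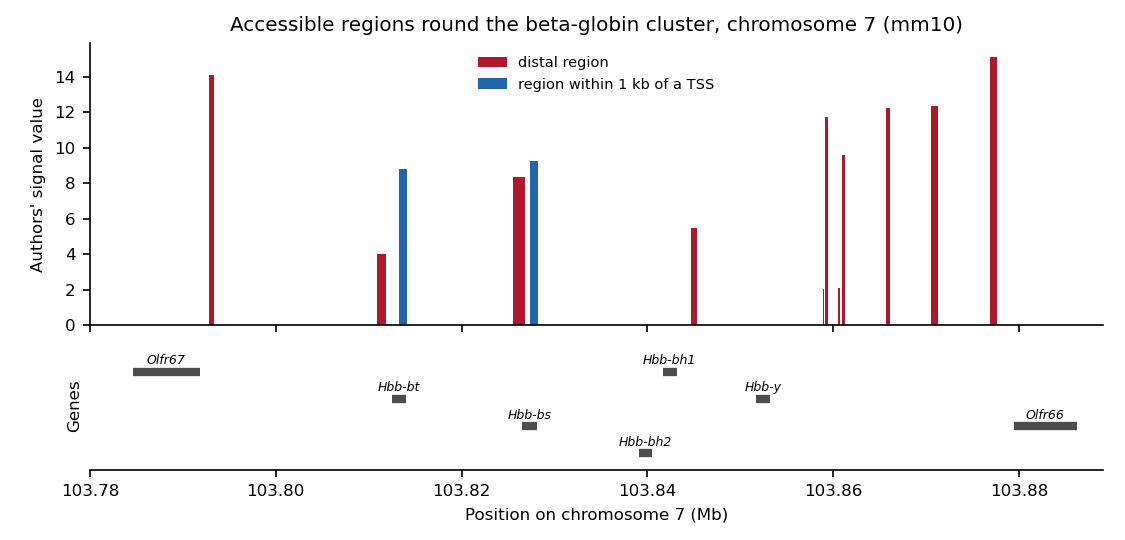
Accessible regions of the pooled IDR-thresholded list round the beta-globin cluster on chromosome 7 (mm10, position in Mb), with bar height the authors' signal value and bar width the region's width; genes are drawn below. Promoter regions (blue) stand at Hbb-bt and Hbb-bs, none stands at Hbb-bh1 or Hbb-y, and distal regions (red) reach a signal of 15.1 on the right.

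Hepatoblast genes did not pass the test for the number of distal regions in the thresholded list. Secreted-protein genes had 1.43 ± 1.43 (28 genes) against 1.04 in random lists (adjusted p = 0.355, permutation) and hepatoblast transcription factors 1.13 ± 1.49 (23 genes) against 0.852 (adjusted p = 0.533, permutation). The secreted-protein ratio to random lists, 1.38, turned to 0.942 within 100 kb, 0.91 above the median signal and 0.501 without replicate 2. Both were higher in the pooled pseudoreplicated list, where the ratios to random lists were 1.59 (adjusted p = 0.0281) and 1.68 (adjusted p = 0.0498), and so were endothelial genes (ratio 1.88, adjusted p = 0.0112), all by permutation. Endothelial genes had 1.00 in the thresholded list (adjusted p = 0.916, permutation).

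Of the reference lists, cell cycle genes (2.36 against 1.04, adjusted p = 0.00383) and housekeeping genes (2.36 against 1.07, adjusted p = 0.00591) had more distal regions, by permutation. Hox genes, also a reference list (0.154 against 1.33), and olfactory receptor genes (0.175 against 1.13) had fewer (adjusted p = 0.00092 each, permutation). Members of both lists lie in clusters and share neighbourhoods, so the permutation counts them as more separate than they are. The remaining lists did not pass the test against random lists (adjusted p from 0.145 to 0.974, permutation): postnatal hepatocyte metabolism had a mean of 1.40, oncofetal growth 1.07, megakaryocyte 1.75, macrophage 0.545, granulocyte 1.56, lymphoid 0.545, stellate 0.455, cholangiocyte 0.538, neuron 0.545, muscle 1.00, other epithelium 0.682 and germline 1.05. In the regions above the median signal, the progenitor, cell cycle and housekeeping calls were lost (adjusted p = 0.106, 0.125 and 0.125, permutation) and 3 lists remained higher. The housekeeping call was also lost without replicate 2 (adjusted p = 0.131) and within 100 kb (0.0512), and the progenitor call within 20 kb (0.176) and with the conservative list (0.0673), by permutation.

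**Figure D3:**
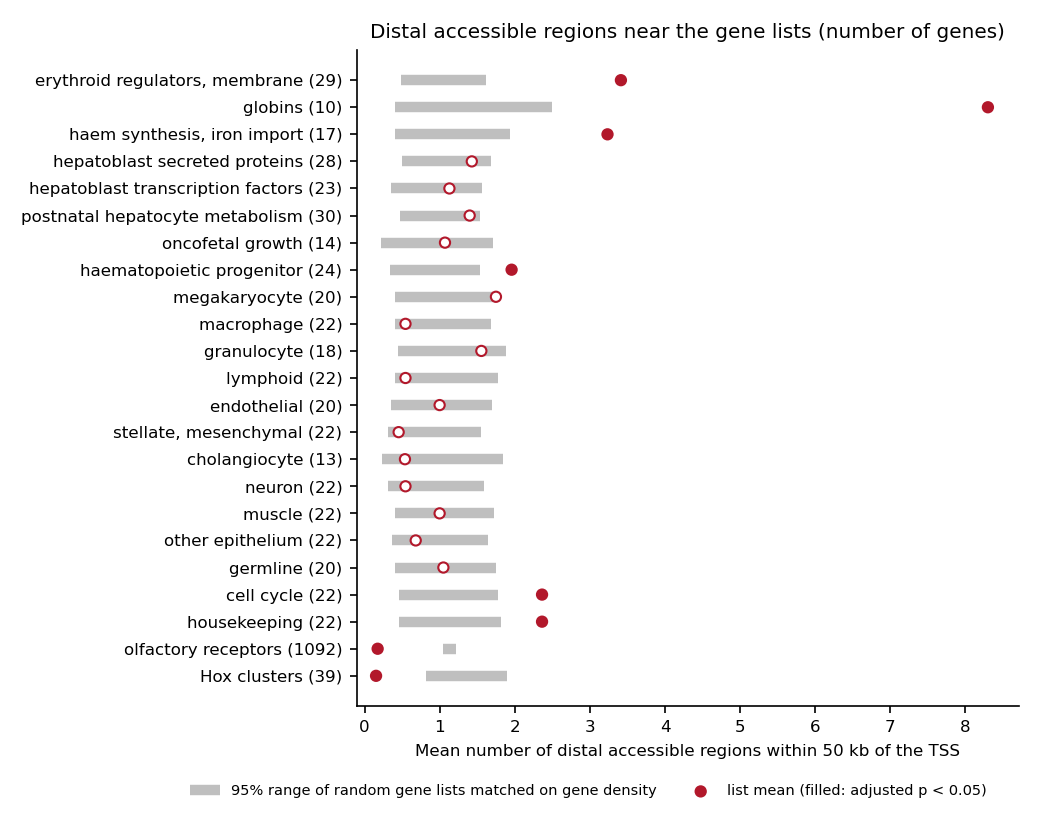
Mean number of distal accessible regions of the pooled IDR-thresholded list within 50 kb of the TSS for each gene list (circles, filled where the adjusted p is under 0.05), against the 95% range of 10000 random lists matched on gene density (grey bars). Globins (8.30), erythroid (3.41) and haem (3.24) genes lie to the right of their ranges, and both hepatoblast lists lie inside them.

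The 10 genes with the most distal regions fell partly into shared neighbourhoods. Abt1, with 16 distal regions within 50 kb, Btn1a1 with 15 and Btn2a2 with 12 are neighbours on chromosome 13. BC107364 and Nol4l had 14 each, Aqp1, which encodes the water channel of red cells, had 13, and Bri3bp and Dhx37, neighbours on chromosome 5, had 12 each. Olfr64 (13) and Olfr65 (12) are olfactory receptor genes beside the beta-globin cluster and had no promoter region of their own. Aqp1 had no thresholded promoter region in either replicate.

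The strongest distal regions were short, and 7 of the 10 lay within 100 kb of a protein-coding gene start. The highest signal, 58.8, was in an intergenic region of chromosome 2 (69355469 to 69355735), 13 kb from the start of Abcb11. The next were near Pak3 on the X chromosome (143482934 to 143483180, signal 56.7), in an intron 34.4 kb from the start of Rtl10 on chromosome 16 (18533121 to 18533398, 51.8), and in intergenic sequence 2140 kb from Cdh20 on chromosome 1 (102628115 to 102628398, 48.9) and 1766 kb from G6pd2 on chromosome 5 (60042692 to 60043153, 45.8). The nearest genes of the other 5 were Epm2a, Gm5426, Igf2bp3, Hic2 and Frmd4a, with signals from 39.4 to 44.1.

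Motifs that erythroid transcription factors bind were enriched at the distal summits. A match does not show which factor of a family was bound, and the hepatoblast transcription factor list also held GATA factors. The GATA motif, bound by GATA1 and GATA2, lay within 100 bp of 68.3% of the 13152 distal summits against 30.02% of 24248 flanking windows (odds ratio 5.02, 95% interval 4.80 to 5.26). GATA paired with an E-box, the composite site of GATA1 and TAL1, was present in 17.8% against 1.60% (odds ratio 13.4, 12 to 14.9), the KLF motif, bound by KLF1, in 13.2% against 2.90% (5.12, 4.67 to 5.6), and the NFE2 motif in 2.40% against 0.190% (13, 9.5 to 17.7). All 4 passed Fisher's exact test (largest adjusted p = 2.21e-94) and kept their direction against random windows of the same GC content, where the odds ratio of GATA was 6.86 and that of KLF 2.94.

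Other blood motifs were enriched less. RUNX was at 3.87% of summits against 2.2% of flanks (odds ratio 1.79, adjusted p = 1.24e-19), PU.1 at 2.46% against 1.48% (1.68, adjusted p = 1.07e-10) and ETS at 0.152% against 0.0701% (2.17, adjusted p = 0.0326), by Fisher's exact test. Against GC-matched windows the PU.1 odds ratio was 1.17 (adjusted p = 0.0867, exact test) and that of ETS, with 20 matches at summits, 2.0 (adjusted p = 0.128, exact test), so that both calls were lost. The ETS call was also lost with windows of 50 and 150 bp (odds ratio 2.17 and 1.75), in the conservative list (1.87), without replicate 1 (1.85), with every summit (1.67) and above the median signal (1.27). The adjusted p of these ran from 0.0713 to 0.862, exact test. Above the median signal the PU.1 call was lost too (1.18, adjusted p = 0.351, exact test). Among general motifs, CTCF was at 2.68% against 0.243% (odds ratio 11.3), NRF1 at 0.129% against 0.0165% (7.84) and NFY at 5.69% against 3.58% (1.63). The NRF1 call, on 17 matches, was lost above the median signal (3.82, adjusted p = 0.121, exact test). RFX, fixed as a motif of other tissues, was also higher, at 0.464% against 0.161% (2.89), and against GC-matched windows (1.65, adjusted p = 0.0306, exact test).

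Among hepatoblast motifs, HNF1 was rare but strongly enriched, and HNF4A and FOXA were slightly enriched. HNF1 was at 0.160% of summits against 0.0206% of flanks (odds ratio 7.75, 95% interval 2.92 to 20.6; adjusted p = 4.58e-06), HNF4A at 1.19% against 0.887% (1.35, 1.1 to 1.66; adjusted p = 0.00779) and FOXA at 5.77% against 5.0% (1.16, 1.06 to 1.28; adjusted p = 0.00235), by Fisher's exact test. CEBP did not pass (1.43% against 1.65%, adjusted p = 0.128, exact test) but was lower with a window of 50 bp (odds ratio 0.715, adjusted p = 0.0203) and without replicate 1 (0.801, adjusted p = 0.0311), by the same exact test. ONECUT was lower (0.806% against 1.44%, adjusted p = 1.31e-07, exact test) but not against GC-matched windows (adjusted p = 0.666). TEAD (odds ratio 0.875), OTX (0.433) and OCT (0.778) were lower, MEF2 and REST did not pass (adjusted p = 0.0777 and 0.751, exact test), and the P63 motif had no match in summit or flanking windows.

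The TEAD call was lost without replicate 1, without replicate 2 and above the median signal (adjusted p = 0.0881, 0.200 and 0.162, exact test), and the OCT call with windows of 50 and 150 bp (0.197 and 0.293) and against GC-matched windows. The TEAD odds ratio stayed near its main value in these settings (0.884, 0.875 and 0.834). That of OCT was 0.776, 0.901 and 1.12. The summits were richer in G and C than the flanks (51.2% against 45.1%). Against GC-matched windows HNF4A (odds ratio 1.77, adjusted p = 3.47e-05) and FOXA (1.48, adjusted p = 4.15e-11) were higher than against flanks, and HNF1 had no match in those windows (adjusted p = 2.31e-06), by Fisher's exact test. The HNF4A call was lost when either replicate was left out (adjusted p = 0.166 and 0.40) or the window was 50 bp (0.311, exact test), and its odds ratio was 0.806 at the regions above the median signal. The FOXA call was lost without replicate 1, without replicate 2 and above the median signal (adjusted p = 0.0881, 0.0830 and 0.922, Fisher's exact test).

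**Figure D4:**
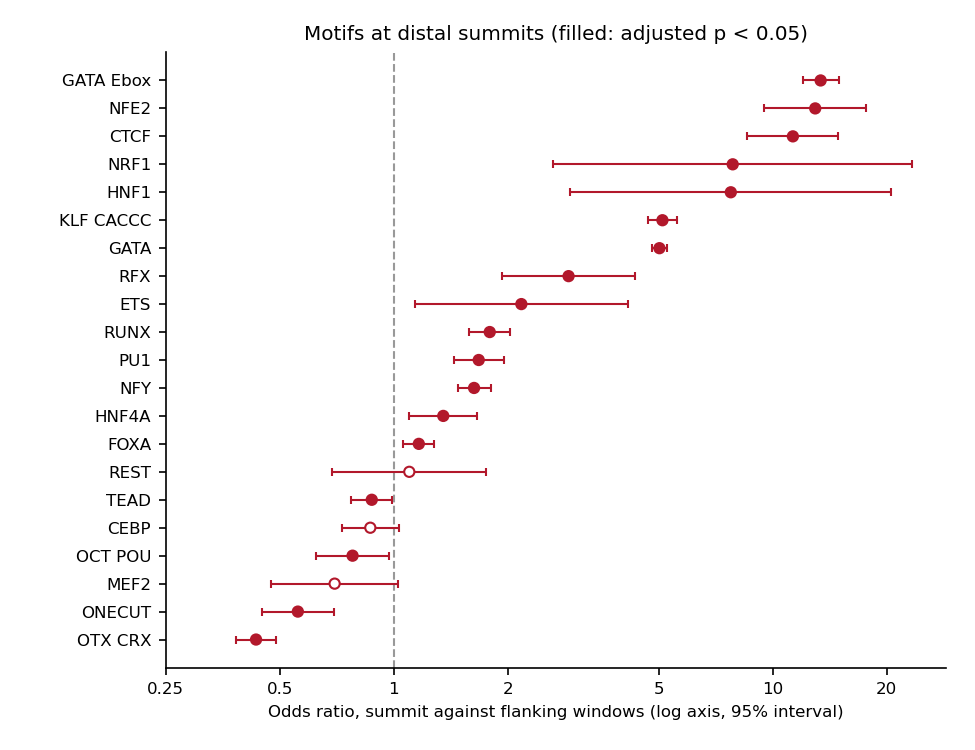
Odds ratio (log axis, 95% interval) of a motif match within 100 bp of 13152 distal summits against 24248 flanking windows, for the 21 motifs with a match, filled where the adjusted p is under 0.05. GATA with E-box (13.4), NFE2 (13) and CTCF (11.3) are highest, and OTX (0.433) is lowest.

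The next comparison took as blood genes only the erythroid, globin and haem lists, not the progenitor or other blood lineage lists. Regions near both these and the hepatoblast lists were left out. No motif told distal regions near these blood genes from those near hepatoblast genes past the threshold. GATA was at 74.6% of the 173 distal regions near blood genes and at 55.4% of the 56 near hepatoblast genes (odds ratio 2.36, 95% interval 1.26 to 4.43; adjusted p = 0.175, Fisher's exact test over 22 motifs). GATA with an E-box was at 22.0% against 7.14% (3.66, 1.24 to 10.8; adjusted p = 0.175, exact test), and HNF4A at 1.16% against 7.14% (0.152, 0.0271 to 0.854; adjusted p = 0.241). None of the 22 motifs passed, with 3 at an unadjusted p under 0.05. GATA passed with the conservative list (odds ratio 3.14, adjusted p = 0.0444) and without replicate 2 (7.19, adjusted p = 0.0248), by the same exact test.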

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

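The test of strongly significant regions of low signal was chosen after the result was seen; the alignment test of the top ranked region was chosen before.

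The 2 pooled IDR-ranked lists held regions on unplaced or unlocalised scaffolds, 92 in the first and 100 in the second, which no comparison used and no thresholded list contained. The region with the highest −log10 p of the pooled ranked lists, 15141, was absent from the pooled IDR-thresholded and pseudoreplicated lists. With this top region among them, 724 and 776 chromosomal regions of the first and second ranked lists had no counterpart of the same start and end in the pooled replicated or pseudoreplicated lists. Partial overlaps were not counted as counterparts here.

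The top ranked region lay on chromosome 1 (24611586 to 24616158, 4573 bp) with a signal of 3.18. A candidate explanation is a nuclear copy of mitochondrial DNA that takes up mitochondrial reads, and 100% of its bases aligned to the mitochondrial chromosome by blastn. Among the 20 pooled IDR-thresholded regions with the highest −log10 p, both of the 2 with a signal value under 10 aligned to the mitochondrial chromosome (chromosome 2, 22588593 to 22590230, signal 8.70, and 22587515 to 22588359, signal 6.70), and so did 74.3% of the region with the highest −log10 p of that list (chromosome 12, 97061366 to 97061856, 13617), whose signal of 28.7 was not low. In all, 12 of the 25955 pooled thresholded regions aligned over most of their length. No biological explanation was tested, and read counts, which the lists lack, would be needed to show where these reads came from.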

How the results depend on the processing

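The alternatives with every summit and with 1 member per 50 kb gene cluster were chosen after the data were seen. No paired analysis was possible because the series held 1 group. The lists carry no read counts, so what sequencing depth limits could not be measured. Of the alternatives, 265 promoter list results, 228 distal list results, 158 motif results and 131 results on blood against hepatoblast regions kept their direction and their side of the threshold. Where values moved, the cause was not tested.

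The shares of replicate 1 and replicate 2 regions found in the other replicate were 91.0% and 60.9% with 50% reciprocal overlap and 91.8% and 61.5% with summits within 100 bp, 2 rules that do not apply to the Jaccard index. With the Jaccard index added last, they were 94.98%, 59.9% and 58.8% in the pseudoreplicated lists, 94.6%, 59.4% and 58.7% in the IDR-ranked lists, 99.1%, 66.4% and 57.4% above the median signal, and 85.8%, 83.8% and 67.1% at equal list length. Spearman's rho was 0.954 for the p column and 0.928 in the pseudoreplicated lists. Regions of replicate 1 alone numbered 1466 with 50% reciprocal overlap, 11 against the pseudoreplicated and 10 against the IDR-ranked list of replicate 2, and regions of replicate 2 alone 2173 and 2158 against those of replicate 1.

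Shares in promoters, exons, introns and intergenic sequence were 44.6%, 3.80%, 31.6% and 19.9% with promoters of ± 500 bp, 54.9%, 2.30%, 25.3% and 17.5% with ± 2 kb, 35.1%, 4.00%, 37.0% and 23.9% in the pseudoreplicated list, and 60.7%, 2.46%, 21.8% and 15.0% for every summit. In the conservative list promoters, introns and intergenic sequence held 52.4%, 27.0% and 17.8%. With each replicate left out, the ranges were 51.2 to 62.2%, 2.17 to 2.86%, 21.2 to 27.8% and 14.4 to 18.05%.

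For promoters, the odds ratio of the megakaryocyte list, now past the threshold, was 0.324 with ± 500 bp, 0.330 in the conservative list, 0.130 above the median signal, 0.323 with the summit in the window and 0.160 with gene starts alone. In the pseudoreplicated lists the odds ratio was 2.18 for hepatoblast secreted proteins and 1.36 for hepatoblast transcription factors, both reversed, as were 3.2 for oncofetal and 1.03 for progenitor genes, and 0.580 for endothelial genes. In the conservative list the hepatoblast lists reversed to 1.14 and 1.08, the progenitor list to 1.17, and the cholangiocyte list passed at 0.180, as it did without chemoreceptor genes in the background (0.202). Above the median signal the haem (1.74) and postnatal (0.381) calls were lost, and the oncofetal (0.0855) and progenitor (0.108) lists passed. Gene starts alone ended the transcription factor call (0.40). Against genes of the same CpG deciles, calls were lost for hepatoblast secreted proteins (0.627), postnatal (0.634), macrophage (0.635), granulocyte (0.124), lymphoid (0.542) and muscle genes (0.403), and gained for oncofetal (0.226) and cholangiocyte genes (0.291), and the uncalled globin (3.81) and megakaryocyte (1.3) lists reversed. The globin list also reversed with ± 2 kb (1.84) and with 1 member per cluster (1.27). With each replicate left out, the odds ratio ranged from 0.210 to 0.988 for hepatoblast secreted proteins and from 0.551 to 0.906 for hepatoblast transcription factors.

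For distal regions, the progenitor ratio to random lists fell under the threshold within 20 kb (2.06), in the conservative list (2.03) and above the median signal (2.25), the housekeeping ratio within 100 kb (1.71) and above the median signal (2.02), and the cell cycle ratio above the median signal (1.98), where 3 lists stayed higher against 6. With each replicate left out, the housekeeping ratio ranged from 1.95 to 2.32. In the pseudoreplicated list hepatoblast secreted proteins (1.59), hepatoblast transcription factors (1.68) and endothelial genes (1.88) passed. Ratios of uncalled lists reversed within 20 kb for granulocyte (0.788), muscle (0.569) and germline genes (0.504), within 100 kb for hepatoblast secreted proteins (0.942) and macrophage genes (1.02), above the median signal for the same lists (0.91 and 1.06), and in the conservative list for muscle genes (0.874). With each replicate left out they ranged from 0.501 to 1.37 for hepatoblast secreted proteins and from 0.868 to 0.875 for muscle genes. With 1 member per 50 kb cluster, 2 of the 10 globins were left and the counts of higher and lower lists stayed at 6 and 2.

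For motifs, 2 were lower against GC-matched windows, compared with 4 against flanks, and OCT reversed there to an odds ratio of 1.12, MEF2 to 1.44 and REST to 0.666. REST, uncalled throughout, also reversed with a 50 bp window (0.897), in the conservative list (0.763) and with each replicate left out (0.808 to 0.904). Above the median signal 9 were higher, compared with 14, and HNF4A reversed to 0.806. Between regions near blood and hepatoblast genes, 1 motif passed in the conservative list, and 0 to 1 with each replicate left out. Uncalled motifs reversed there for NFE2 within 20 kb (0.935) and NFY with a 150 bp window (0.621). ETS had an odds ratio of 1.19 within 100 kb, but with no match in either set within 50 kb it had no direction to reverse. With each replicate left out the odds ratio ranged from 0.359 to 1.12 for KLF, 0.667 to 2.15 for NFE2, 0.395 to 1.54 for RUNX, 0.528 to 1.05 for CTCF, 0.495 to 2.48 for NFY and 0.528 to 2.8 for OTX.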

Other observations

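The tests of hepatoblast promoters missing from replicate 1, of motif matches at the flanking rate, of CpG content, of the authors' threshold and of accessibility in a minority of the cells were chosen after the results were seen, as were the comparisons by signal quartile and of the strongest regions.

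Across quartiles of signal, the GATA motif was commoner at stronger distal regions and the CTCF motif at weaker ones. From the lowest to the highest quartile of signal, 3288 distal regions each, the GATA motif was at 55.2%, 62.96%, 72.8% and 82.3% of summits (95% Wilson intervals 53.5 to 56.9% in the lowest and 80.9 to 83.5% in the highest). GATA paired with an E-box, the composite site of GATA1 and TAL1, went from 9.28% to 29.0%, and KLF from 12% to 15.0%, while NFE2 was at 2.07%, 1.89%, 3.13% and 2.52% with overlapping intervals in the lowest and highest quartiles. At the 100 strongest distal regions GATA was at 73%, GATA with an E-box at 31%, KLF at 12%, NFE2 at 2%, CTCF at 0% and HNF4A at 3%, against 68.3%, 17.8%, 13.2%, 2.40%, 2.68% and 1.19% of all distal regions. The GATA and KLF shares at these 100 lay under the 82.3% and 15.0% of the highest quartile, so their rise did not continue to the very strongest regions. GATA with an E-box lay near its 29.0% there. CTCF, which marks insulators and loop anchors, was at 3.86%, 4.01%, 2.16% and 0.700%, and HNF4A, a hepatocyte lineage regulator, at 1.61% in the lowest and 0.608% in the highest quartile. Of the 10 strongest distal regions, 6 had none of the 22 motifs, among them those near Rtl10 and Hic2.

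Replicate 2 had more accessible regions than replicate 1, with 8523 regions that the thresholded replicate 1 list lacked. A threshold effect is a candidate explanation, since 74.7% of these had a counterpart in the IDR-ranked list of replicate 1. Thinner hepatoblast chromatin in replicate 1 stays open: regions with an HNF4A, HNF1 or FOXA motif had 0.955 times the odds of others of being missing (Mantel-Haenszel over signal deciles, 95% interval 0.796 to 1.15), but the flanking rate alone would give 82.9% of these matches, so the bound set for this test was wrong and it decides nothing. Odds of being missing from replicate 1 were raised near hepatoblast genes against erythroid, globin and haem genes (3.10, 1.36 to 7.10, 45 against 150 regions) and at hepatoblast-list promoters (2.87, 1.05 to 7.88, 25 promoters). These rest on few regions with wide intervals and on 1 pool per side. A different cell makeup of the pools therefore cannot be told apart from other differences between them. The design names no biological difference between the replicates, so none beyond cell makeup was tested.

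Promoters of secreted hepatoblast proteins were rarely open in both thresholded lists. Low promoter CpG content is a candidate explanation (adjusted p = 0.589 against genes of the same CpG deciles, permutation), as is the authors' threshold on the replicate lists, because the odds ratio was 2.18 in their pseudoreplicated lists; the pooled conservative list, also thresholded, gave 1.14. Accessibility in a minority of the cells stays open: the median promoter signal in the pooled pseudoreplicated list was 5.36 for 25 open hepatoblast genes and 12.7 for 29 open erythroid genes, a ratio of 0.421 (permutation p = 2e-05, the smallest these resamples allow), but 5.13% of random open lists of the same CpG content had a lower median. For hepatoblast transcription factors, with a median of 5.93 against 11.4 in such random lists, 0.34% were lower. The design holds no group that separates cell types, so this explanation had no direct test.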
